A study of Homo sapiens with 6 samples.

How the data were processed

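ATAC-seq peak lists of 6 libraries of the KMS-11 line were used, 3 titled as controls and 3 titled with a lentiviral vector and a guide against ATF4. Nuclei were treated with Tn5 transposase after lysis with mild detergents and digitonin, and the released fragments were amplified and size-selected, per the labels' protocols. Peaks were called with MACS2 on hg38, per the submitters' processing notes, separately for each library. The MACS2 version, its settings, the aligner, the filters on reads and any shift of reads for the transposase offset are not given in the sources used here. A shift or extension of reads would move and widen every peak alike within a library.

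Each deposited list gives a position, a summit and 4 values per summit, and several summits can share a peak. The fold enrichment in the deposited lists is a ratio of the pileup at the summit to the caller's local background, each with 1 added. The −log10 p and −log10 q in the deposited lists come from the caller's test within that library, and every listed summit has a −log10 p of at least 2. The score in the deposited lists is 10 times the −log10 p up to a cap of 1000, and was used only to check the columns. These values were used to describe, rank and filter peaks within a list, since they move with the depth of a library. Each list skips 894 to 976 of its rank numbers, so summits of other sequences or removed summits are not analysed here. Chromosome Y and unplaced sequences, with 6 to 16 summits per list, were left out.

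Gene names and positions came from a table of RefSeq genes on GRCh38.p14, the assembly of hg38, with 19970 protein-coding genes on the chromosomes used. The table has no strand, so the planned distance to a transcription start was replaced by the distance to either annotated end of a gene, called a gene end. This deviates from the design set before the data were examined. No genome sequence was used, so the planned search for 16 motifs, among them the ATF4 and NF-kB sites, was not run, and exons and introns were not told apart. Of the 351 list members, 350 had a gene in the table.

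Overlapping peaks were merged within each library to count regions, and over all libraries at a −log10 q of at least 2 to compare them. A region was present in a library when a peak with a −log10 q of at least 2 overlapped it by 1 bp or more, and absent when no listed peak did. Group means of values per library were compared by exact permutation tests, two-sided, in which 3 libraries against 3 cannot give a p under 0.1. Locations were compared by Fisher's exact tests with Benjamini-Hochberg adjustment, against regions found in exactly 3 libraries of mixed groups.

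For each protein-coding gene, bases covered by listed peaks within 10 kb of either end were summed, divided by the total covered length of the library, multiplied by the mean total, and compared as log2(value + 200 bp). Genes covered in at least 3 libraries were tested with limma (lmFit, eBayes with trend and robust settings, Benjamini-Hochberg adjustment, threshold 0.05). Differences on this scale understate the change of genes with little covered DNA. Gene lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. The 18 lists, fixed before the data were examined, held ATF4 targets, amino acid synthesis, amino acid transporters, aminoacyl-tRNA synthetases, endoplasmic reticulum chaperones, NF-kB genes, the BACH1 and NRF2 axis, plasma cell and myeloma genes, coactivators, interferon response, p53, autophagy, cell cycle and housekeeping genes, and markers of B, T and NK, myeloid, and epithelial and stromal cells. Some members stand in 2 lists, such as ASNS, CTH and CBS among ATF4 targets and amino acid synthesis.

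Named items followed a rule fixed before the data were examined. It takes ATF4, BACH1, NFKB2 and RELB, the 10 genes with the largest change in each direction past the threshold, the 8 group-specific regions in each direction with the highest lowest −log10 q, and up to 4 members of each list that pass adjusted over the list alone, or else the 2 with the smallest p. Genes without an official symbol were left out. A second housekeeping gene chosen by this rule is not reported here, and it stays in the list tests and in the counts over settings. Items outside it are said to be chosen after their values were seen.

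The pileup and local background at each summit were recovered from the deposited fold and −log10 p, as the whole number of overlapping tags whose Poisson p, at the background that the fold implies, matched within 0.01 on the −log10 scale. All summits were recovered (100%). The most common local background of a library is its library-wide rate and was used as its depth, 2.15 to 3.52. Lower depth raises the pileup over background that a region needs to be listed, so weak regions are missed first. Pileups served to describe named regions and in the closing tests, not in gene tests. Local background was called flat at 1.5 times that of the library or less.

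Presence patterns were tested on 20000 simulated sites, all recovered, the gene test on simulated data with 200 changed genes, and the recovery of pileups on 19839 simulated summits (100% recovered). Alternatives set before the data were examined covered the threshold, lists of equal length, the overlap rule, the gene window, scaling, pseudocount, filters, the set test, the replicate block and leaving out each library. Flat local background and the gene end with more covered bases were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.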

Results

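KMS-11 is a human multiple myeloma line, a cancer of antibody-secreting plasma cells, and ATF4 is a transcription factor of the response to amino acid shortage and to stress of the endoplasmic reticulum. Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA. There were 3 libraries titled as controls and 3 titled with a lentiviral vector and a guide against ATF4, called the knockdown libraries here. All 3 knockdown libraries bear the same guide label, so no second guide was compared. The sample titles name no vector for the controls and do not say how the guide acts. The title of the study names enhancers bound by ATF4 with the p52 product of NFKB2, and the gene BACH1. The comparison of the 2 groups asks which accessible regions and genes differed when ATF4 was knocked down. The data were 6 lists of peaks, 1 per library, with 220250 to 238246 listed summits on chromosomes 1 to 22 and X. The background pileup, a measure of sequencing depth recovered from each list, was 3.19, 2.79 and 3.52 in control libraries 1, 2 and 3 and 2.51, 2.15 and 2.51 in knockdown libraries 1, 2 and 3. The samples of a group are labelled as biological replicates, and no batch or date was given.

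The gene targeted for knockdown kept its accessible region. The peak over ATF4 (chromosome 22, 39519219 to 39521254, hg38, at an annotated end of the gene) was listed in all 6 libraries, with −log10 q of 302, 332 and 296 in the controls and 112, 119 and 197 in the knockdown libraries. These are the values of the deposited lists, which rank a peak within its own library and move with depth. Accessibility at ATF4 measures neither its RNA nor its protein, so the lists hold no check of the knockdown. Peaks covered 4089 ± 352 bp within 10 kb of the ends of ATF4 in the controls and 3086 ± 714 bp in the knockdown libraries (SD, n = 3 each), a difference of −0.40 on the log2 scale (SE 0.14, limma adjusted p = 0.253). Of the 6 regions within 10 kb, only that over ATF4 was nearest to ATF4, and the others were nearest to RPS19BP1 or MIEF1. The difference is therefore not that of ATF4 alone.

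BACH1, a repressor of genes of haem and oxidant metabolism, had 3 regions within 10 kb of its ends, and 1 of them was found in the control libraries alone. That region (chromosome 21, 29296575 to 29296788), between genes and 2.13 kb from an end of BACH1, had pileups of 78, 72 and 57 in the controls, a −log10 q of 11.5, 9.32 and 3.74 and a fold over local background of 2.61, 2.45 and 1.90. It lay in a stretch of high local background, 9.18 times that of the whole library. The other 2 regions of BACH1, at its annotated end (29298417 to 29299703) and inside the gene (29299946 to 29300899), were found in all 6 libraries. The main regions of NFKB2 (chromosome 10, 102393942 to 102395243), which encodes the precursor of p52, and of its partner RELB (chromosome 19, 45001141 to 45002535) were also found in all 6. A second RELB region inside the gene (45007054 to 45007452) was found in 5 of the 6, and not in knockdown library 1. Peak-covered length within 10 kb of gene ends did not pass the limma test for BACH1 (log2 difference −0.21, SE 0.11, adjusted p = 0.451), RELB (−0.17, SE 0.09, adjusted p = 0.440) or NFKB2 (0.00, SE 0.12, adjusted p = 1.0).

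Many more regions were found in the 3 control libraries alone than in the 3 knockdown libraries alone. The strongest control-only region on flat local background lay inside ASCC1 (chromosome 10, 72208506 to 72209159), 6.85 kb from an end of ANAPC16, which encodes a subunit of the anaphase-promoting complex. Its pileup was 66.0 ± 8.89 (SD, n = 3), its lowest −log10 q was 48.7, and no peak of any knockdown library overlapped it. It lay 64.8 kb from DDIT4, an ATF4 target gene chosen after the values were seen. Inside NUMB, an inhibitor of Notch signalling, a control-only region (chromosome 14, 73414751 to 73415657) had a pileup of 54.0 ± 8.0. Inside GATB, a subunit of the mitochondrial glutamyl-tRNA amidotransferase, another (chromosome 4, 151728011 to 151729166) had a pileup of 55.7 ± 7.02. A control-only region 17.6 kb from the helicase gene DDX10 (chromosome 11, 108958541 to 108959550, between genes) had a pileup of 44.3 ± 2.08. The regions inside ASCC1, NUMB and GATB and near DDX10 had a local background of 1.0 to 1.05 times that of the library.

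The other control-only regions of the highest rank lay on raised local background. These were a region inside GTPBP2 and 1.98 kb from MAD2L1BP (chromosome 6, 43627272 to 43627556), with a pileup of 197 ± 20.01 on 14.9 times the background of the library, and a region inside the potassium channel gene KCNQ1 (chromosome 11, 2703226 to 2703483), with 134 ± 11.5 on 8.57 times. A region inside MTMR12 (chromosome 5, 32276154 to 32276769) had 84.3 ± 3.51 on 3.65 times, and a region 69.3 kb from MRPL14 (chromosome 6, 44043622 to 44044132, between genes) had 71.3 ± 12.7 on 1.87 times. All errors are SDs over the 3 control libraries.

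**Figure D1:**
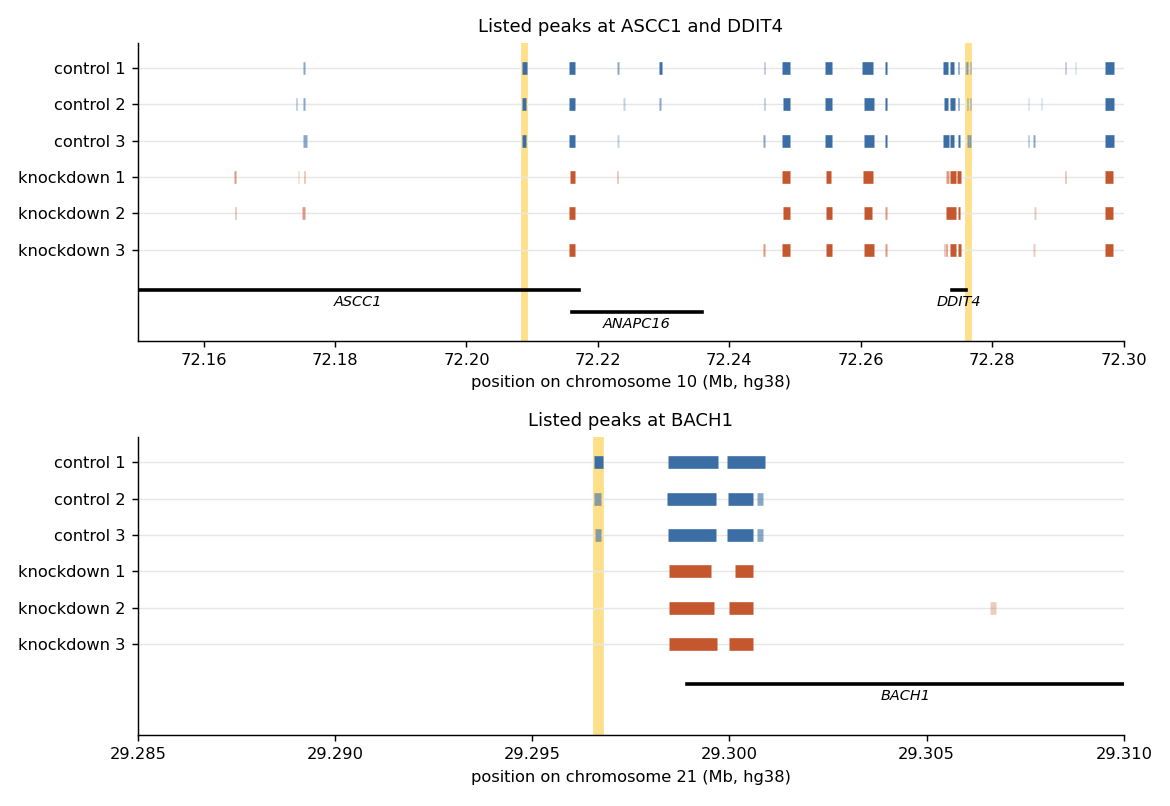
Listed peaks of the 6 libraries at ASCC1 and DDIT4 (chromosome 10) and at BACH1 (chromosome 21), with position in Mb on the x axis. Each block is a listed peak, darker where its −log10 q is higher, black lines are genes, and yellow bands mark regions found in the 3 control libraries and in no knockdown library, among them the one inside ASCC1 from 72208506 to 72209159 and the one 2.13 kb from BACH1.

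The knockdown-only regions were fewer and weaker. The strongest lay inside DUSP10, which encodes a phosphatase of stress-activated kinases (chromosome 1, 221712979 to 221713417, 11.6 kb from a gene end), with a pileup of 33.7 ± 3.51 (SD, n = 3) and a lowest −log10 q of 13.7. Next came a region inside ARHGAP10 (chromosome 4, 147846343 to 147846687, pileup 35.3 ± 8.74) and a region 0.30 kb from GGNBP2 (chromosome 17, 36590150 to 36590415, pileup 32.7 ± 6.11). Regions inside MIA3 (chromosome 1, 222653436 to 222653883, pileup 28 ± 3.46), 35.2 kb from PLG (chromosome 6, 160789249 to 160789874, pileup 31.3 ± 4.04) and inside PRKG1 (chromosome 10, 51066252 to 51066572, pileup 16 ± 1.0) followed. The 2 remaining regions of the 8 highest, with no protein-coding gene end within 100 kb, lay on chromosome 6 (100171925 to 100172322, pileup 19.3 ± 1.53) and on chromosome 3 (20598716 to 20599463, pileup 21 ± 5.57).

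In all, 3247 of 216003 merged regions were found in the 3 control libraries at a −log10 q of at least 2 with no listed peak in any knockdown library, against 221 for the reverse, and 62070 were found in all 6. Regions were compared as found or absent, where an exact permutation test of 3 libraries against 3 cannot go below 0.1, and no test per region was run. The 18 mixed sets of 3 libraries, such as controls 1 and 2 with knockdown 3, held at most 531 such regions. Of them 5 held more than the 221 of the knockdown set, and each of these 5 had 2 control libraries. Mixed sets with 2 knockdown libraries held 72 to 206. With lists shortened to the same 135070 highest-ranked peaks in every library, and any kept peak as presence, the counts were 5356 control-only and 702 knockdown-only. The cut left control library 3 whole and removed weak peaks from the other lists, most from the knockdown lists, which can itself create absences. With any listed peak of the full lists as presence, the like rule, the counts were 4834 and 1341. With presence at a −log10 q of at least 10 they were 316 and 1. The counts grew when a library was left out, to 5804 control-only regions without control library 3 and to 1132 knockdown-only regions without knockdown library 2.

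**Figure D2:**
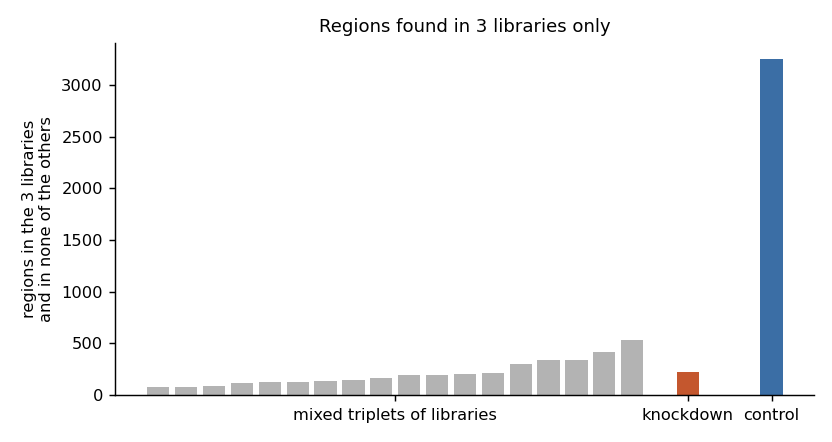
Number of merged regions (y axis) found in 3 given libraries and in none of the other 3, for the 18 mixed sets of libraries (grey), the 3 knockdown libraries (orange) and the 3 control libraries (blue). The control set held 3247 regions and the knockdown set 221, against at most 531 in a mixed set.

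Control-only regions were spread over gene bodies and intergenic DNA, like those inside NUMB and near DDX10, and seldom touched a gene end. Of the 3247, 46.7% lay in gene bodies, 48.9% between genes and 4.43% within 1 kb of an annotated end of a protein-coding gene, against 44.5%, 51.6% and 3.97% of the 3781 regions found in 3 libraries of mixed groups. None of these shares passed Fisher's exact test (two-sided, Benjamini-Hochberg p = 0.204, 0.157 and 0.407, over 6 tests). The gene body share, higher than in mixed regions, and the intergenic share, lower, did pass with any of the 6 libraries left out (Fisher's exact test, Benjamini-Hochberg p = 3.79e-06 to 0.0256 and 8.91e-08 to 0.0159) and with lists of equal length (3.96e-06 and 1.20e-07). Leaving out a library loosened the rule for control-only regions. The mixed background then also took in regions found in fewer than 3 of the remaining libraries. Lists of equal length counted any kept peak as presence. These passes therefore compare other sets of regions and are not repeats of the main test. The knockdown-only regions had 4.07% at gene ends (Fisher's exact test, Benjamini-Hochberg p = 0.860). Regions found in all 6 libraries, such as those over ATF4, BACH1 and RELB, lay at gene ends in 21.1% of cases. With gene ends widened to 5 kb, the control-only share was 18.1%, higher than in mixed regions, and passed Fisher's exact test (Benjamini-Hochberg p = 3.02e-10). The intergenic share of 43.4%, lower than in mixed regions, also passed Fisher's exact test (Benjamini-Hochberg p = 0.000202). These tests treat regions as units and compare these libraries only.

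Each knockdown list held more regions than each control list, and fewer strong ones. Merged regions numbered 148836 ± 13220 in the controls and 168611 ± 4114 in the knockdown libraries (SD, n = 3 each), a difference of 19775 (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). At a −log10 q of at least 10 the order turned, with 69887 ± 4012 against 48512 ± 3224 regions (exact permutation p = 0.1). Distal regions, more than 1 kb from a gene end, numbered 131537 ± 12799 and 150946 ± 4074 among all listed regions, and the share at gene ends was 11.7% ± 0.77 and 10.5% ± 0.24 (exact permutation p = 0.1 for both). Both turned at stricter thresholds, to differences of −7250, −21259 and −20099 distal regions and 0.48, 4.04 and 5.99 points at a −log10 q of at least 2, 5 and 10. Peaks of the controls were wider, with a median of 325 ± 22.5 bp against 254 ± 7.55 bp, and covered 69.3 ± 2.00 Mb against 63.5 ± 0.46 Mb (exact permutation p = 0.1 for both).

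**Figure D3:**
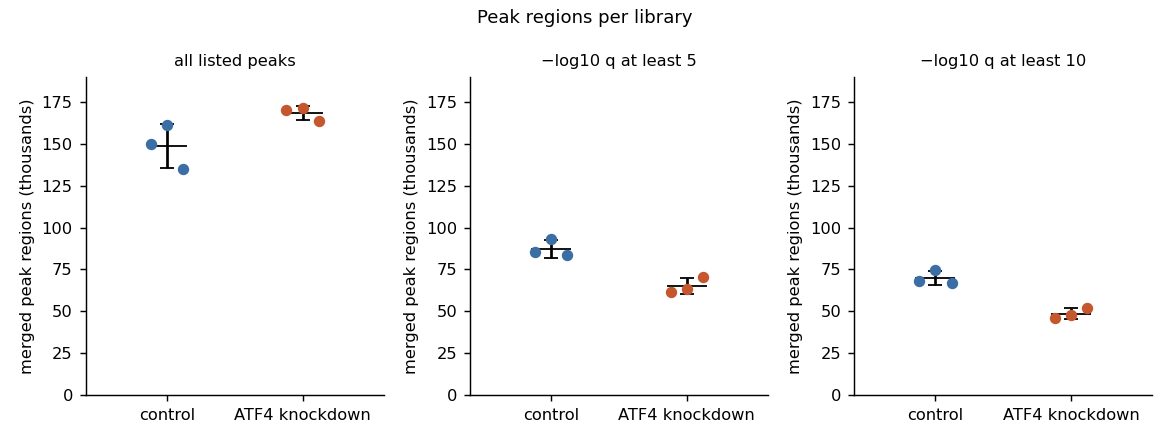
Merged peak regions per library (y axis, in units of 1000) for all listed peaks and for peaks with a −log10 q of at least 5 and at least 10. Points are libraries, and bars are the mean and SD of the 3 libraries of a group. The knockdown libraries lie above the controls for all listed peaks and below them at both stricter thresholds.

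Depth and signal moved with the group. The background pileup was 3.17 ± 0.37 in the controls and 2.39 ± 0.20 in the knockdown libraries (SD, n = 3 each), a ratio of 0.754 (exact permutation p = 0.1). At the 67785 regions listed in all 6 libraries, the median pileup over background was 22.8 ± 3.58 and 14.7 ± 1.32, a ratio of 0.644 (exact permutation p = 0.1). The ratio was 0.735 for common regions at gene ends and 0.645 for distal ones.

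At gene level, the transporter gene SLC7A5, which encodes a carrier of large neutral amino acids, had less peak-covered DNA in the knockdown libraries, and HSP90AA1, a cytosolic chaperone gene, had more. No gene passed a limma adjusted p of 0.05 among 18602 protein-coding genes, and 1689 lower and 910 higher genes had an unadjusted p under 0.05. Because none passed, the genes named here are the 8 that shared the smallest adjusted p of 0.0556, and they were chosen after their values were seen. Covered length within 10 kb of the ends of SLC7A5 was 4627 ± 153 bp in the controls and 2968 ± 70.7 bp in the knockdown libraries (log2 difference −0.61), and of HSP90AA1 3602 ± 66.2 bp and 5492 ± 424 bp (0.58; SD, n = 3 each). The −log10 q of the strongest peak within 10 kb moves with depth, which was lower in the knockdown libraries. At SLC7A5 it was 124, 114 and 128 in the controls and still higher, at 143, 135 and 156, in the knockdown libraries. At HSP90AA1 it was 306, 308 and 355 in the controls and 212, 211 and 288 in the knockdown libraries. The peak over ATF4 fell as well, so the fall at HSP90AA1 cannot be read as an opposite change at that gene. Covered length was also lower at ASCC1 (2282 ± 41.2 and 1162 ± 62.4 bp, −0.87) and at the ubiquitin-binding protein gene UBQLN2 (2806 ± 100.3 and 1585 ± 51.8 bp, −0.75). The same held for the sodium channel gene SCNN1B (2598 ± 89.9 and 884 ± 249 bp, −1.39) and the extracellular matrix gene TNR (3426 ± 110.6 and 1677 ± 275 bp, −0.96). The window of ASCC1 takes in the control-only region of 654 bp inside that gene, so its lower covered length partly repeats that region. SEMG1 and KIR2DL4 had no covered base in the controls and 1246 ± 12.2 and 1072 ± 287 bp in the knockdown libraries, made of weak peaks with a −log10 q of at most 4.21 and 5.84.

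Covered length was scaled by the total of each library, and the count of genes past the threshold moved with this choice. Without scaling, 690 genes were lower and 48 higher, and without scaling on lists of equal length 1547 were lower and 34 higher, with the median of all genes at −0.14 and −0.17 on the log2 scale in place of −0.02. More genes were higher than lower at a −log10 q of at least 5 (545 lower and 5284 higher, median 0.19). The same held, by a small margin, within 50 kb (383 lower and 428 higher, median −0.04). At a −log10 q of at least 5 the knockdown libraries held fewer regions (65082 against 87478), with a share at gene ends 4.04 points higher. Values there are relative to each library's own total at that threshold, so the 5284 cannot be read as genes that gained strong peaks. In simulated data with 200 changed genes, the test found 9% of changes of 0.5 and 70% of changes of 1 on the log2 scale, with 0 false calls. The changed genes were drawn from those with a mean above 1000 bp, the added 200 bp included, so genes with less covered DNA were not tried. Variation was shuffled within each gene, which removes shifts shared by many genes, so the 0 false calls do not cover such shifts.

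Genes of plasma cells and myeloma had less covered DNA as a group in 1 of 3 set tests. Of 27 tested members, 20 had a lower mean in the knockdown libraries, the median log2 difference was −0.12, and limma's camera test passed with its preset correlation (adjusted p = 0.00899), but not with an estimated correlation between genes (adjusted p = 0.693) or in fry (adjusted p = 0.174). The call was also lost within 2 kb of gene ends, where the median turned to 0.05 (adjusted p = 0.799), at a −log10 q of at least 5 (median 0.17, adjusted p = 0.684) and at the gene end with more covered bases (−0.09, adjusted p = 0.0993). Adjusted over the list alone in limma, 6 members were lower and 1 was higher, against 0 over all genes tested. The lower ones included TXNDC5, a disulfide isomerase of secretory cells (6724 ± 359 and 5162 ± 460 bp, −0.37, list-alone adjusted p = 0.0114), the costimulatory receptor CD28 (2432 ± 341 and 1516 ± 250 bp, −0.62, 0.0125) and the B-lineage coactivator POU2AF1 (4676 ± 585 and 3347 ± 351 bp, −0.46, 0.0125). The higher one was the lymphoid transcription factor IKZF1 (1598 ± 114 and 2328 ± 102 bp, 0.49, list-alone adjusted p = 0.0114). All errors are SDs with n = 3.

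ATF4 target genes had less covered DNA in the same test, with 23 of 27 members lower, a median of −0.15 and a camera adjusted p of 0.0196, a call lost with an estimated correlation (adjusted p = 0.693) and in fry (adjusted p = 0.180). It was also lost within 2 kb (adjusted p = 0.162), within 50 kb (adjusted p = 0.361), at the gene end with more covered bases (adjusted p = 0.171) and at a −log10 q of at least 5, where the median was 0.15 (adjusted p = 0.602). The calls of NF-kB genes and aminoacyl-tRNA synthetases were lost in the same 4 settings, with quantile normalization (adjusted p = 0.0917 for both) and at a mean covered length of at least 1000 bp (adjusted p = 0.0528 for both). No member passed adjusted over the list alone. The 2 with the smallest p went opposite ways, the stress-response gene NUPR1 (320 ± 140 and 819 ± 191 bp, 0.99, list-alone adjusted p = 0.166) and the secreted hormone gene STC2 (3242 ± 135 and 2607 ± 343 bp, −0.30, 0.166; SD, n = 3). The NF-kB pathway and its targets were lower in 20 of 28 members, with a median of −0.08 and a camera adjusted p of 0.0196, also lost with an estimated correlation (adjusted p = 0.693) and in fry (adjusted p = 0.208). Again none passed adjusted over the list alone. Its smallest p-values were at the inhibitors of NF-kB signalling TNIP1 (4283 ± 104 and 3387 ± 296 bp, −0.32, list-alone adjusted p = 0.0732) and TNFAIP3 (4479 ± 228 and 3818 ± 309 bp, −0.22, 0.133; SD, n = 3). The aminoacyl-tRNA synthetases were lower in 19 of 21 members, with a median of −0.11 and a camera adjusted p of 0.0237, lost with an estimated correlation (adjusted p = 0.693) and in fry (adjusted p = 0.174). Among them LARS1, the leucyl-tRNA synthetase, was lower adjusted over the list alone (2173 ± 230 and 1340 ± 182 bp, −0.63, list-alone adjusted p = 0.0190; SD, n = 3). Without control library 3 the camera adjusted p was 0.0725 for plasma cell genes, 0.0727 for ATF4 targets and synthetases and 0.125 for NF-kB, so none of the 4 passed. The ATF4 targets also missed it without knockdown library 2 (0.0868). The synthetases missed it without knockdown library 1 (0.0754) and without knockdown library 3 (0.0532).

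**Figure D4:**
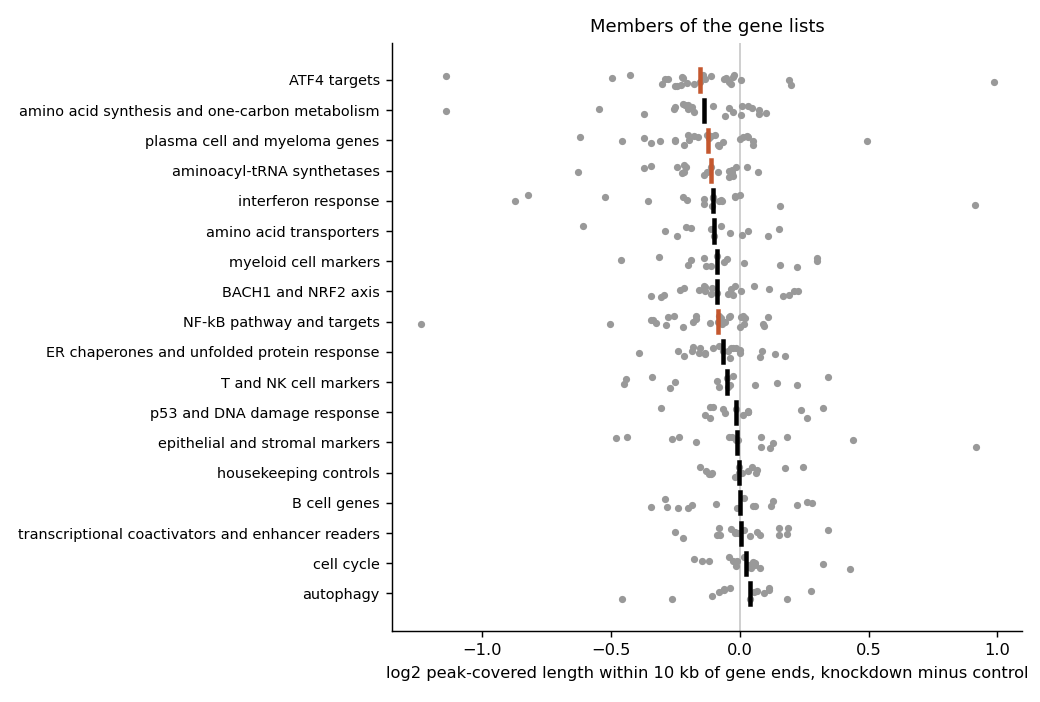
Log2 difference in peak-covered length within 10 kb of gene ends, knockdown minus control (x axis), for the members of the 18 gene lists (grey points) with each list's median (bar, orange for the 4 lists past the camera test with its preset correlation). The medians of those 4 lists lie between −0.15 and −0.08.

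The remaining lists did not pass the camera test. Amino acid transporters had a median of −0.10 in 13 tested members (camera adjusted p = 0.0614), among them SLC7A5, which was lower adjusted over the list alone (list-alone adjusted p = 0.000109). Amino acid transporters passed without scaling (camera adjusted p = 0.0184), without scaling on equal lists (camera adjusted p = 0.0256) and without control library 2 (camera adjusted p = 0.0192), all at the preset correlation. In the main setting they missed it with an estimated correlation (camera adjusted p = 0.782) and in fry (adjusted p = 0.187). Genes of amino acid synthesis and one-carbon metabolism had a median of −0.14 in 22 members (camera adjusted p = 0.0680). The smallest p-values were at the urea cycle gene ASS1 (2103 ± 83.9 and 1393 ± 266 bp, −0.55, list-alone adjusted p = 0.0794; SD, n = 3) and at SHMT2 (−0.20, 0.224). This list passed without knockdown library 1 at the preset correlation (camera adjusted p = 0.0476). In the main setting it missed with an estimated correlation (camera adjusted p = 0.693) and in fry (adjusted p = 0.174). Interferon response genes were lower in 17 of 19 members with a median of −0.11 (camera adjusted p = 0.0967), and IFIT2 was lower adjusted over the list alone (1155 ± 162 and 541 ± 113 bp, −0.87, list-alone adjusted p = 0.0328; SD, n = 3). Chaperones of the endoplasmic reticulum and the unfolded protein response had a median of −0.06 (camera adjusted p = 0.236), with EDEM1 at −0.24 and HERPUD1 at −0.14 (list-alone adjusted p = 0.329 for both). The BACH1 and NRF2 axis had a median of −0.09 (camera adjusted p = 0.398), with the iron exporter gene SLC40A1 at −0.34 (list-alone adjusted p = 0.169) and MAFK at −0.31 (0.25).

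Lists of other functions did not pass the camera test either. Medians were 0.00 for transcriptional coactivators, in which KMT2C was at −0.22 and EP300 at 0.34 (list-alone adjusted p = 0.252 for both), 0.02 for cell cycle genes, with CCNE1 at 0.43 (0.259) and CCNA2 at 0.32 (0.313), and −0.00 for housekeeping genes, with TBP at 0.17 (0.674). The p53 list had a median of −0.02, with MDM2 at 0.32 (list-alone adjusted p = 0.0850) and CDKN1A at −0.31 (0.0881), and autophagy genes one of 0.04, with ATG3 lower adjusted over the list alone (2217 ± 37.1 and 1561 ± 15.1 bp, −0.46, list-alone adjusted p = 0.0124; SD, n = 3). Camera adjusted p-values of these 5 lists lay between 0.496 and 0.841. Markers of other cells gave camera adjusted p-values of 0.841 to 0.870. Their medians were 0.00 for B cells (BCL6 −0.28 and CD79B −0.34, list-alone adjusted p = 0.0559 and 0.0613), −0.05 for T and NK cells (CD3E −0.44 and CD4 −0.45, 0.228 for both), −0.09 for myeloid cells (CD68 0.22 and ELANE −0.20, 0.199 for both) and −0.01 for epithelial and stromal cells (KRT19 0.44 and VWF 0.92, 0.478 for both). Median, mean and test differed in sign for B cell genes (median up, mean and test down), autophagy (mean down, median and test up), p53 (median down, mean and test up), epithelial markers (median down, mean and test up) and housekeeping genes (median and mean down, test up).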

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

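The gene end with more covered bases and flat local background were tried after seeing the data, and all other settings had been set before. Counted over settings, 591 of 678 values of named genes and 262 of 324 of gene lists kept direction and side of the threshold, and 29 and 34 turned direction. Of gene lists 24 lost a call and 4 gained one, and 58 values of named genes gained one, 20 of them without scaling on equal lists, 17 without scaling, 10 at a −log10 q of at least 5 and 9 at 50 kb. The window of ATF4, which takes in regions nearest to other genes, was called at a −log10 q of 5 (−0.24, limma adjusted p = 0.0415, against a median of 0.19 over all genes), and SLC7A5 in 6 of 18 alternatives. Unless a cause is given, it was not tested. The lower depth of the knockdown libraries limits what the absence of a weak peak can show, and the motif search was not run for want of a genome sequence.

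Peak regions per library, 19775 more in the knockdown group among all listed peaks, turned to −7762 at a −log10 q of at least 2, −22395 at 5 and −21375 at 10. Distal regions went to −7250, −21259 and −20099 and the share at gene ends, −1.19 points, to 0.48, 4.04 and 5.99. Listed summits differed by −12139 and covered length by −5.87 Mb. The replicate numbers left no clear pairing in covered length, where deviations of same-numbered libraries correlated at 0.0166, 0.0011 and 0.0262 across genes. Controls 1 and 3 correlated best with their own number, but control 2 did so with knockdown 1 (0.0125) and knockdown 2 with control 3 (0.0031). This check cannot show whether samples were handled in pairs. With the replicate block the difference was 19775 (exact sign-flip permutation p = 0.25, the smallest possible), 0 genes and 4 lists were called, and no other call changed.

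Control-only regions, 3247, became 1211 at a −log10 q of at least 5, 316 at 10, 5356 with equal lists, 344 with presence taken from the 67535 strongest peaks of those lists and 6498 with overlap of at least 50%, and ranged from 4505 to 5804 with a library left out, which loosens the rule. Knockdown-only regions, 221, became 9, 1, 702 and 10 under the first 4 of these and 1341 with any listed peak, and ranged from 336 to 1132. Flat local background left 2290 and 184. Against regions in all 6 libraries the shares of control-only regions at gene ends (4.43%) and between genes (48.9%) and of knockdown-only regions at gene ends (4.07%) and in gene bodies (39.4%) lay on the other side of the background share. All of these but the last passed Fisher's exact test (Benjamini-Hochberg p = 7.40e-156, 8.63e-21, 1.40e-12 and 0.782), as did control-only regions in gene bodies (3.67e-20) and knockdown-only regions between genes (2.16e-06). With gene ends at 5 kb and mixed regions as background, the control-only share was 18.1% at gene ends (higher) and 43.4% between genes (lower). Both now passed the test. It was 38.5% in gene bodies, on the other side of the background, as was the knockdown-only share of 12.2% at gene ends. Knockdown-only shares also crossed it at a −log10 q of 5 (44.4% in gene bodies and between genes, 9 regions) and with equal lists (2.85% at gene ends). With a library left out the gene end shares ranged from 4.19% to 4.64% for control-only and 2.97% to 4.76% for knockdown-only regions. The control-only shares in gene bodies and between genes then passed Fisher's exact test for each library left out, as they did with equal lists. With a library left out, the mixed background also took in regions found in fewer than 3 of the remaining libraries, so these are not repeats of the main test. Without knockdown library 3, Fisher's exact test also passed for control-only regions at gene ends (Benjamini-Hochberg p = 0.0387) and for knockdown-only regions in gene bodies (0.00637) and between genes (0.00387), and with equal lists for knockdown-only regions between genes (0.0274).

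Genes with less and more covered length, 0 and 0 in limma (1689 and 910 unadjusted), were 2 and 0 at 2 kb, 383 and 428 at 50 kb, 690 and 48 without scaling, 1547 and 34 without scaling on equal lists, 545 and 5284 at a −log10 q of at least 5, where the median of all genes was 0.19, 5 and 1 with a pseudocount of 1000 bp, 0 and 1 for genes covered in 1 library and 5 and 1 at a mean of at least 1000 bp. Lists called, 4, were 0 at 2 kb, at a −log10 q of 5, with the end with more covered bases, with an estimated correlation and with fry, 1 at 50 kb, 2 with quantile normalization and at a mean of 1000 bp, and 0 to 5 with a library left out. Without scaling 5 were called, on lists as deposited and on equal lists, the fifth being amino acid transporters. Of 18 alternatives, the camera adjusted p passed in 14 for plasma cell genes (0.00117 to 0.799), 12 for ATF4 targets (0.00929 to 0.602), 11 for NF-kB (0.00221 to 0.799) and 9 for aminoacyl-tRNA synthetases (0.0107 to 0.992).

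Lists whose camera test turned direction are given with their median log2 difference. At a −log10 q of 5 these were aminoacyl-tRNA synthetases (0.19), chaperones (0.21), the BACH1 axis (0.19) and epithelial markers (−0.0305). At 2 kb they were chaperones (0.0284), the BACH1 axis (0.01) and plasma cell genes (0.0504). At 50 kb they were B cell (−0.0051), myeloid (−0.0205), epithelial (−0.0516), p53 (−0.0524), autophagy (−0.10) and housekeeping genes (−0.0346). Without scaling they were myeloid (−0.20), p53 (−0.13), autophagy (−0.077) and housekeeping genes (−0.12), and without scaling on equal lists T and NK (−0.17), myeloid (−0.28), p53 (−0.18), autophagy (−0.14) and housekeeping genes (−0.14). With quantile normalization it was epithelial markers (0.0041), at a mean of 1000 bp myeloid markers (−0.0896), and with the end with more covered bases coactivators (−0.0365) and autophagy (−0.0201). With a library left out coactivators ranged from −0.0393 to 0.0587, epithelial markers from −0.0448 to 0.0451, p53 from −0.0722 to −0.0033, autophagy from −0.0102 to 0.0789 and myeloid markers from −0.17 to −0.0191.

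Among named genes, the log2 difference turned at a −log10 q of 5 for BACH1 (0.0864), RELB (0.22), SHMT2 (0.0115), EDEM1 (0.13), HERPUD1 (0.0409), TNIP1 (0.10), SLC40A1 (0.28), KMT2C (0.18), BCL6 (0.005), ELANE (0.10), KRT19 (−1.28), CDKN1A (0.0876) and ATG3 (0.0758), against a median of 0.19 over all genes there. It turned at 2 kb for RELB (0.0494), ASS1 (0.26), TXNDC5 (0.0558), POU2AF1 (0.15) and CD4 (0.41), and at 50 kb for NFKB2 (−0.12), KMT2C (0.12) and KRT19 (−0.0629). NFKB2, near 0 as reported, also turned without scaling (−0.12), without scaling on equal lists (−0.18) and with a pseudocount of 20 bp (−0.0005), and ranged from −0.14 to 0.0826 with a library left out. With the end with more covered bases it turned for SHMT2 (0.0515), SLC40A1 (0.062) and ATG3 (0.0571).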

Other observations

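The tests of depth, of signal over background and of distance to ATF4 target genes were chosen after the counts of regions had been seen, as was the naming of regions and genes in this part. The comparison with other splits of the libraries was planned, and its reading was written down after the counts were known.

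Of the genes of the ATF4 target list, ASNS, the asparagine synthetase gene, had a control-only region on flat local background 5.76 kb from a gene end (chromosome 7, 97845497 to 97845914, hg38), with pileups of 25, 34 and 17 in control libraries 1, 2 and 3. Weaker control-only regions, on local background of at most 1.32 times that of the library, included those 15.4 kb from KLHL24 (pileups 14, 19 and 16), 38.7 kb from CHAC1 (19, 17 and 19) and 50.6 kb from ATF3 (17, 19 and 18). Control-only regions at DDIT4 (0.01 kb and 0.48 kb from a gene end), ADM2 (8.03 kb) and inside LONP1 had pileups of 76 to 123 on local background 8.49 to 14.5 times that of the library. The single knockdown-only region of the list, 54.8 kb from DDIT3, had pileups of 49, 48 and 57 on 9.78 times the background. Peak-covered length within 10 kb of ASNS was 480 ± 233 bp in the controls and 147 ± 254 bp in the knockdown libraries (SD, n = 3 each, log2 difference −1.14, limma adjusted p = 0.400). No region found in all 6 libraries lay within 10 kb of the annotated ends of ASNS, against 6 within 100 kb. The value thus rests on little covered DNA, and it takes in the control-only region 5.76 kb from a gene end.

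SIK1, which encodes a salt-inducible kinase, was the nearest gene of 5 control-only regions, more than any other gene, followed by HERPUD2, KCNMA1, ST3GAL1 and TOX2 with 4 each. No test was run on these counts, which grow with the length of the surrounding DNA. The SIK1 regions, 3 of them inside the gene (chromosome 21, 43415790 to 43416086, 43419541 to 43419936 and 43422633 to 43422920), had pileups of 22 to 72 on local background 2.91 to 8.33 times that of the library. On chromosome 4 above 50 Mb, weak peaks (−log10 q below 2) numbered 27.1, 37.5 and 21.5 per Mb in control libraries 1, 2 and 3 and 51.0, 49.1 and 43.0 in knockdown libraries 1, 2 and 3, and below it 7.28, 10.6 and 5.61 and then 15.7, 17.1 and 13.5. Pileups at gene ends there were 1.72 ± 0.02 (above 50 Mb) and 1.01 ± 0.02 (below) times the median of all chromosomes, and distal pileups 0.90 ± 0.04 and 0.87 ± 0.02 times (SD, n = 6 libraries). At gene ends the value was 0.66 ± 0.02 on chromosome 13, 0.76 ± 0.02 on chromosome 11 and 1.25 ± 0.04 on chromosome 7.

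Control-only regions, such as those inside ASCC1, NUMB and GATB, outnumbered knockdown-only ones by 3247 to 221. Lower depth of the knockdown libraries alone was argued against by pairs of libraries: of the regions of a control at a −log10 q of 5 or more, at least 11.19% had no peak in a knockdown library at a depth ratio of 0.77 or more, against at most 5.81% within groups at 0.91 or less, with both limits set after the values were seen, and over all depth ratios at least 10.07% against at most 7.15% within groups. Within the controls the loss was lowest at the lowest depth ratio (2.17% at 0.793) and highest at the highest (7.15% at 1.26). The limit of 0.91 therefore gave no baseline matched for depth. The 2290 flat regions absent from all 3 knockdown libraries lay in the 553.8 to 4385.9 expected from depth alone. They also lay in the 1778.2 to 9282.5 expected with 1 signal factor per library (0.578, 0.645 and 0.663), a model whose range held a simulated loss of 5% of regions too. Both ranges took, at each pileup, the higher of the 2 groups' rates of absence, which raises their ends. The factors came from 10200 regions listed in all 6 libraries with a −log10 q of at least 20 in each control, a choice that favours high control values. A count within these ranges therefore carries little weight for either model. Absences per library numbered 8386, 6987 and 6448. Depth alone gave fewer (4385.9, 6196.3 and 4385.9) and the factors more (10797.3, 11225.8 and 9282.5). At a pileup of at least 30 the count of 35 of 13668 lay above the 21.7 of depth alone and within the 8.3 to 349.7 of the factors, which gave 703.9, 843.8 and 349.7 absences per library where 396, 251 and 172 were seen, and whose range (0.5 to 185.2) missed the 0 absences of simulated regions with none lost. A signal lower throughout and a loss at single regions therefore cannot be told apart, and an effect of the ATF4 knockdown stays open, untested, under either.

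Knockdown-only regions on flat local background, such as the one inside PRKG1, numbered 184, within the 31.8 to 713.1 expected from depth alone and above the 0.1 to 65.2 expected with the signal factors. Those factors came from the same regions, chosen by high control values. They gave 127.1, 65.2 and 120.5 absences per control library where 797, 522 and 1049 were seen, so their range is too low to decide. The 18 mixed sets of 3 libraries held 57 to 430 such regions. Every mixed set above the 184 had more control than knockdown libraries. Every mixed set with more knockdown than control libraries lay below the 184. Mixed sets thus still follow the grouping in part, so their range cannot decide. An effect of the knockdown and variation between libraries therefore cannot be told apart for these regions. The regions inside DUSP10 and ARHGAP10 and near GGNBP2 lay on local background 1.72 to 2.51 times that of the library and were not part of this test.

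The real grouping gave 3468 group-specific regions in both directions, more than the highest of the other splits of the 6 libraries (603), so 1 of 10 splits reached that number. It gave 4 gene lists past the camera test against at most 1 in another split, so 1 of 10 splits reached that number, and 0 genes past the limma test, as did all 10 of 10 splits (highest other 0). With 10 splits no share under 0.05 could be reached.

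The hypothesis that ATF4 target genes hold more control-only regions than other genes was tested against mixed regions. Of the control-only regions 5 lay within 10 kb of a target gene, such as ASNS, DDIT4 and LONP1, and 0 of the mixed regions (Fisher's exact test, two-sided, p = 0.0210, Benjamini-Hochberg p = 0.625 over 36 tests of 18 lists and 2 windows). Within 100 kb the counts were 15 and 7 (Fisher's exact test, p = 0.0521, Benjamini-Hochberg p = 0.625). The hypothesis was not borne out after adjustment, with too few regions near the list to exclude it.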
